A study of Oryza sativa with 8 samples.

How the data were processed

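Shoots of transgenic rice seedlings were profiled on 8 single-colour arrays, 2 lines per genotype at 0 h and 2 h of nitrate. The deposited scanner files give each spot as an intensity on a linear scale, made with Agilent Feature Extraction 9.1.3.1 per the file headers (9.1 per the submitters' processing notes). The processed signal in these files is an intensity with background subtracted and spatial trends removed, with a surrogate value where a spot was not above background, per the file headers. The deposited series table holds, when set against the scanner values, the processed intensity divided by the 75th percentile of its array; it is linear and not centred on genes, and its column medians lay between 0.201 and 0.217.

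The log2 processed signal of each spot was taken and the 75th percentile of the array subtracted. Control spots, 59 probes named as controls and outlier spots were left out, and spots of one probe were averaged, giving 42418 probes for 29024 genes. A gene was represented by its brightest probe over all arrays, and kept if that probe was well above background on both arrays of at least 1 group. This left 22676 genes, of which 7640 had more than 1 probe. Gene descriptions are those in the files and can be old. None of the 952 RefSeq accessions in the files was found in the reference table, and a genome was not used here, so no coordinates are given.

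Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in one model of all 8 arrays with 4 residual degrees of freedom, Benjamini-Hochberg adjustment and a threshold of 0.05. Each SE comes from the spread shared by all 4 groups of this model, so it does not measure the lines compared alone. Beside an SE, n is the number of lines per genotype. Where a gene was not well above background on any array of the dimmer group, a fold is a bound, written at least N-fold. It sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the gene's own. The labels name separate transgenic lines but not the plants or pools behind an array, so p-values measure the spread between these samples. The method was tested on simulated data of 22615 genes. In the control nitrate comparison it recovered 0% of genes changed 2-fold, 46% changed 4-fold and 74% changed 16-fold, and in the interaction 8% changed 4-fold and 62% changed 16-fold. The simulated noise was independent between arrays and took each gene's fitted spread as exact. It held no shared line or slide differences, so recovery in the real data can differ.

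Each slide held 4 arrays, 1 of each group: slide 1 lines 56 and 55, slide 2 lines 60 and 51. The day of scanning coincided with the slide, so it was not run as a separate block. Within a genotype, line and slide cannot be told apart. Arrays of the 2 times pair by line per the labels. The difference between the lines at 0 h correlated across genes with that at 2 h, with r = 0.20 in the controls and 0.71 in the overexpressors. Between the genotypes, whose lines share slides, it correlated with r = 0.50 at 0 h and 0.24 at 2 h.

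The comparisons, the 22 gene lists and the rule for named genes were fixed in advance. Lists were tested with camera at a preset correlation of 0.01, over 105 tests of 21 lists in 5 comparisons, again with an estimated correlation, under which 0 of the 14 calls held, and with fry. The lists cover nitrate reduction, nitrate transport, ammonium assimilation and asparagine synthesis, ammonium transport, reductant supply, organic acid supply, GARP factors, phosphate starvation, light-harvesting and photosystem proteins, chlorophyll synthesis, cytokinin, clock genes, heat shock proteins, pathogenesis-related proteins, sulfate, starch and trehalose, cytosolic ribosomal proteins, core histones, early auxin response, root markers, seed storage proteins and reference genes. A listed locus whose description names another protein was dropped by a rule fixed in advance but applied after the descriptions were seen. It removed Os02g0662100 from the root markers, which left too few to test, while 2 nitrate transport loci described as similar to BCH2 were kept; both opposite choices were run.

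Named genes are, per comparison and direction, up to 8 of the largest changes that passed, moved the same way in both lines and have a description naming a protein. Where no gene passed, the 4 of smallest unadjusted p in each direction are named as not passing. Up to 4 members of each list and NIGT1 were added. Alternatives set before the data were examined were normexp on mean and background signal (offset 50), quantile normalization, median scaling, the series table, no filter on dim probes, a filter on all arrays, the mean over probes, the slide as a block, the line as a replicate block, the line as a random block, an intensity trend, only the arrays compared, a 4-fold selection for the carry-over, and leaving out each array. Alternatives chosen after seeing the data were normexp without spots darker than their background, leaving out both 0 h arrays of slide 2, the slide block for lists, and the opposite choices for the root and BCH2 loci.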

Results

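Gene expression was measured in rice shoots on 8 single-colour Agilent arrays, one per RNA sample. The plants were transgenic lines that overexpress NIGT1, a transcriptional repressor of the GARP family whose transcript is induced by nitrate, and lines that carry the vector alone. Seedlings had been kept on distilled water, and shoots were taken before (0 h) or 2 h after transfer to 10 mM potassium nitrate. Each of the 4 groups held 2 lines, control lines 56 and 60 and overexpressor lines 55 and 51. The 75th percentile of the processed signal was lowest, 542, on the array of control line 60 at 0 h, and highest, 1883, on that of overexpressor line 51 at 2 h. Between 73.4% and 80.3% of spots were well above background, and the number of arrays limits the precision of every value.

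The NIGT1 transcript (Os02g0325600) was examined first. In the control lines its mean scaled log2 signal was -4.31 at 0 h and -0.09 after nitrate, a difference of 4.22 ± 0.54 (SE, n = 2 lines) seen in both lines that did not pass the test (adjusted p = 0.0962). This SE holds the spread of all 4 groups, not that of the control lines alone. Control lines 56 and 60 had -4.34 and -4.28 at 0 h, and 0.01 and -0.19 at 2 h. Overexpressor lines 55 and 51 lay further apart at 2 h, at -3.98 and -2.19. In the overexpressors the transcript was not well above background on either array at 0 h and rose at least 18.7-fold after nitrate (adjusted p = 0.0286, higher in 2 of 2 lines). Set against the controls, the overexpressor signal at 0 h was at least 8.00-fold lower (adjusted p = 0.99994), and at 2 h the difference was -2.99 (adjusted p = 0.839). Neither passed, and the sign was the same on both slides. Without the 2 h array of overexpressor line 51 the 2 h difference was -3.89 (adjusted p = 0.0200), but the overexpressors then had 1 array at 2 h, that of line 55, and the spread came only from the other groups. The array carries 2 probes for this locus with 1 sequence, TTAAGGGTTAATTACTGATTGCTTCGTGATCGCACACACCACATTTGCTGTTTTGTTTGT, which has a stop codon in every forward reading frame and so cannot lie wholly in coding sequence. Whether the transgene carries this sequence is not stated in the labels, so the probes do not check the overexpression. On the 2 h array of overexpressor line 55 the probes disagreed, at -8.71 and -3.98. The nitrate call in the overexpressors was lost with the mean over both probes (4.48, adjusted p = 0.283) and under several other settings, with adjusted p between 0.00884 and 0.841 over all settings.

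**Figure D1:**
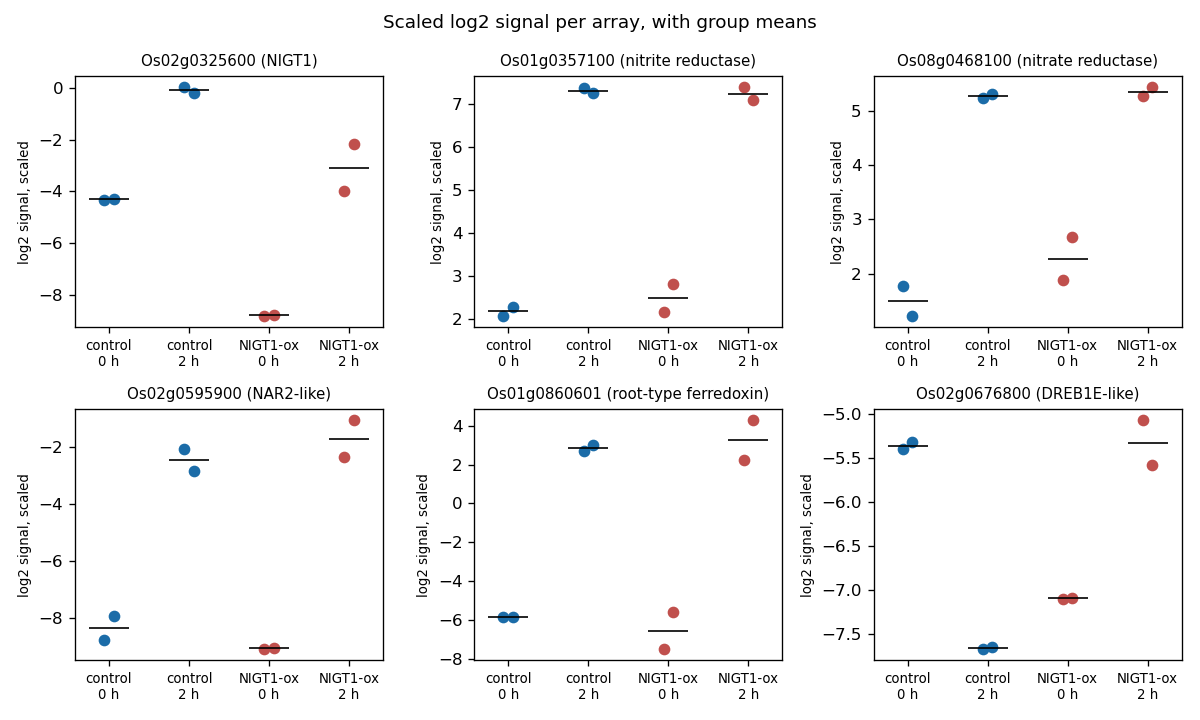
Scaled log2 signal of 6 genes on each of the 8 arrays, by group, with points for single lines and bars for group means. The group means of NIGT1 were -4.31 and -0.09 in the controls at 0 h and 2 h, and -8.79 and -3.08 in the overexpressors, whose 0 h values were not well above background.

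The nitrate response was asked first in the control lines. Genes of nitrate reduction rose: ferredoxin-nitrite reductase (Os01g0357100), which reduces nitrite to ammonium, 35.1-fold (log2 5.13 ± 0.27, SE, n = 2 lines, adjusted p = 0.00606), and a nitrate reductase gene (Os08g0468100) 13.7-fold (adjusted p = 0.0309). Genes that supply reductant rose as well, namely a root-type ferredoxin (Os01g0860601, log2 8.70 ± 0.81, adjusted p = 0.0389), the root isozyme of ferredoxin-NADP reductase (Os03g0784700, 20.8-fold), 6-phosphogluconate dehydrogenase (Os11g0484500, 12.4-fold) and a transaldolase (Os01g0926300, 4.01-fold). A NAR2-like component of high-affinity nitrate transport (Os02g0595900) rose at least 24.1-fold. A second nitrate reductase gene (Os02g0770800) had a difference of 6.22 that did not pass (adjusted p = 0.109).

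Among transcription factors, genes similar to LOB domain protein 39 (Os03g0609500, 101-fold, adjusted p = 0.00732) and MybSt1 (Os05g0442400, at least 46.7-fold, adjusted p = 0.00371) rose. So did alpha-amylase 3D (Os08g0473900, at least 19.5-fold), a phosphoenolpyruvate carboxykinase (Os10g0204400, at least 32.6-fold), a dioxygenase similar to RAMOSUS1 (Os01g0566500, 21.8-fold) and a gene similar to a hevamine-type chitinase (Os01g0860500, 12.2-fold). A gene similar to DREB1E (Os02g0676800) fell at least 4.69-fold (adjusted p = 0.0435). In all, 22 genes were higher and 3 lower by limma, while 431 were at least 2-fold higher and 432 lower on both slides, without a test. The count was 4 without line 56 at 0 h, 0 without line 56 at 2 h, 4 without line 60 at 0 h and 1 without line 60 at 2 h. With the line as a replicate block 8 genes passed, of which 5 were also called without the block.

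Of 14 genes of nitrate reduction 3 rose in the controls, 8 when adjusted over the list alone, with a median of 0.98 (adjusted p = 1.34e-08, and adjusted p = 0.178 with an estimated correlation). Of 35 reductant supply genes 4 rose, 6 when adjusted over the list alone (median 0.19, adjusted p = 0.000632, and adjusted p = 0.316 with an estimated correlation). Of 13 nitrate transport genes 1 rose, 4 when adjusted over the list alone (median 0.57, adjusted p = 0.00399, and adjusted p = 0.559 with an estimated correlation). The transport median was -0.69 under the normexp setting, and the call was also lost with the series table (0.24, adjusted p = 0.118), with the filter on all arrays (0.20, adjusted p = 0.176) and without line 56 at 0 h (0.60, adjusted p = 0.191). None of the cytosolic ribosomal protein genes passed alone, 0 also when adjusted over the list alone, while 231 of 266 were above 0. The median over the 265 with a value on every array was 0.43 (adjusted p = 4.13e-17, and adjusted p = 0.606 with an estimated correlation). It was 0.26 on slide 1 and 0.61 on slide 2.

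Clock genes, which a 2 h interval in the light also moves, held GIGANTEA (Os01g0182600, difference 1.14, adjusted p = 0.207) and an LHY-like gene (Os04g0583900, -1.52, adjusted p = 0.207), neither passing, and 1 gene higher and 1 lower when adjusted over the list alone. Shoots kept for 2 h without nitrate were not analysed here, so time and nitrate are not separated. The slides differed in size of response: 1685 genes changed at least 2-fold in line 56 on slide 1 and 4820 in line 60 on slide 2. Loci listed as root markers differed in both directions between the 0 h arrays of slide 2 and slide 1. In the controls and overexpressors the differences were -1.28 and -2.42 for Os03g0667500, 1.64 and 0.18 for Os02g0745100, and 2.81 and 2.61 for Os02g0662100, whose description names another protein. Without both 0 h arrays of slide 2, an alternative chosen after seeing the data, limma called 0 genes in the controls, with 1590 at an unadjusted p under 0.05, and 0 in the overexpressors, with 2129.

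In the overexpressors nitrite reductase rose 26.9-fold after nitrate (log2 4.75 ± 0.27, SE, n = 2 lines, adjusted p = 0.00781) and the nitrate reductase gene Os08g0468100 8.45-fold (adjusted p = 0.0377). The root-type ferredoxin rose by log2 9.79 ± 0.81 (adjusted p = 0.0225), the root ferredoxin-NADP reductase 19.4-fold, 6-phosphogluconate dehydrogenase 14.5-fold and glucose-6-phosphate dehydrogenase (Os07g0406300), which makes NADPH, 9.74-fold. The NAR2-like gene rose at least 49.1-fold, LOB domain protein 39 70.6-fold, alpha-amylase 3D at least 43.5-fold, the RAMOSUS1-like dioxygenase 48.4-fold and the chitinase-like Os01g0860500 16.9-fold. Genes similar to RAP2.6 (Os12g0168100) and to eIF-6 (Os01g0280500) rose at least 35.6-fold and at least 18.5-fold. In all, 47 genes were higher and 2 lower by limma, and 615 were at least 2-fold higher and 357 lower on both slides, without a test. The count was 7 without line 55 at 0 h, 11 without line 55 at 2 h, 5 without line 51 at 0 h and 32 without line 51 at 2 h, of which 12 were higher, 20 lower and 12 also called with all arrays. It was 100 with the slide as a block and 7 with the line as a replicate block, of which 5 were also called without a block.

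Of 14 nitrate reduction genes 3 rose in the overexpressors, 8 when adjusted over the list alone (median 1.22, adjusted p = 1.23e-07, and adjusted p = 0.178 with an estimated correlation). Of 13 nitrate transport genes 1 rose, and 6 were higher and 2 lower when adjusted over the list alone (median 0.64, adjusted p = 0.00263, and adjusted p = 0.559 with an estimated correlation). That call was lost with the series table (0.21, adjusted p = 0.114), with the filter on all arrays (0.18, adjusted p = 0.217) and without the 2 loci similar to BCH2 (0.21, adjusted p = 0.0566). The reductant supply list did not pass (adjusted p = 0.184), with a median of -0.10 and a mean of 0.67, although 5 members rose, 6 when adjusted over the list alone, and the list passed with fry (adjusted p = 0.00171). Cytosolic ribosomal proteins had a median of 0.58 (adjusted p = 7.45e-20, and adjusted p = 0.606 with an estimated correlation), 0.25 on slide 1 and 0.92 on slide 2. Light-harvesting and photosystem proteins had a median of -0.46 with 2 of 41 genes above 0 (adjusted p = 3.75e-06, and adjusted p = 0.559 with an estimated correlation), -0.37 on slide 1 and -0.55 on slide 2. In both lists 0 genes passed alone and 0 when adjusted over the list alone, and the light-harvesting call was lost with quantile normalization (-0.15, adjusted p = 0.0575).

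**Figure D2:**
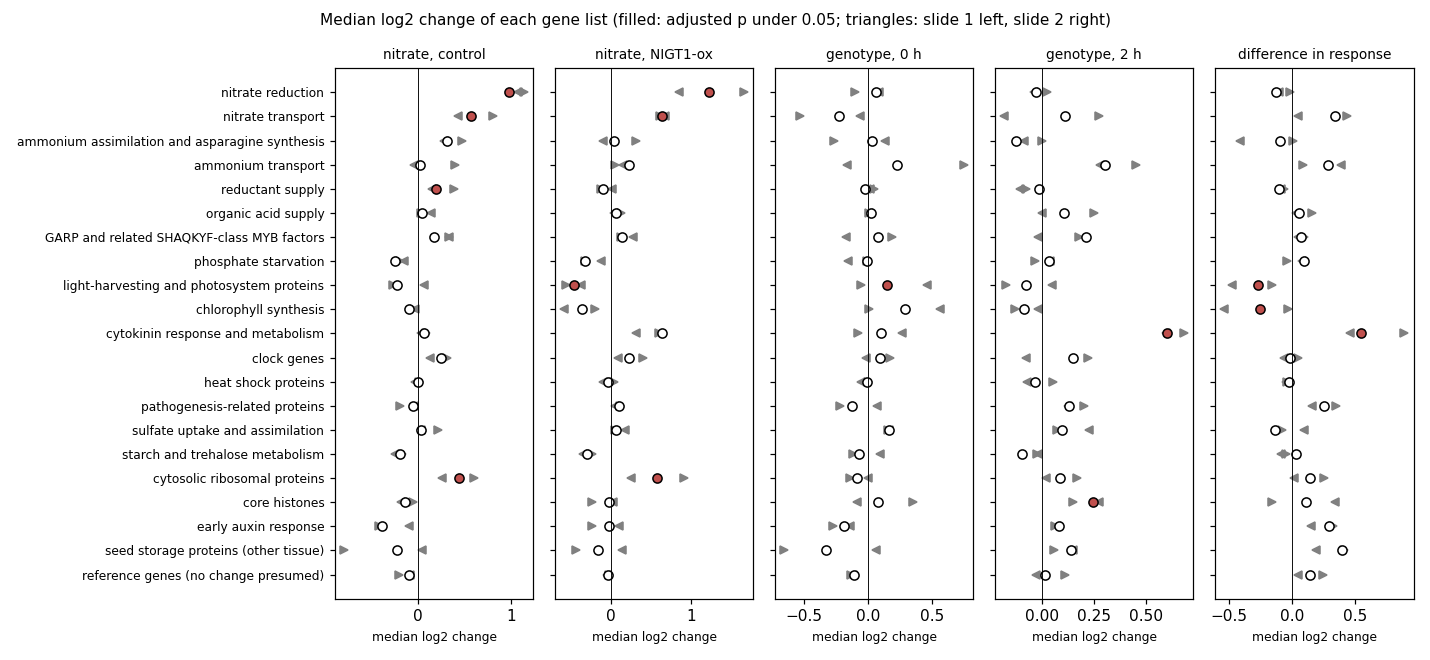
Median log2 change of the 21 tested gene lists in each of the 5 comparisons, as circles filled where the adjusted p was under 0.05, with triangles for the values on slide 1 (pointing left) and slide 2 (pointing right). Nitrate reduction had medians of 0.98 in the controls and 1.22 in the overexpressors.

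Of the genes higher after nitrate, 20 were called in both genotypes, where independent lists of these sizes would share 0.0456, and 0 of the lower genes were shared. Both comparisons used the same spread for each gene, so the lists are not independent and 0.0456 is not a fair baseline. Over the 54 genes called in either genotype, 51 had the same sign in both, and the smallest adjusted p for a difference in response was 0.137. Of the 54, 25 had an unadjusted p under 0.05 for that difference, against 321 of all 22676 genes. Choosing genes by tests on the same arrays affects this number, so it does not settle whether the responses differ. The 853 genes at least 2-fold up in control line 56 had a median log2 change of 1.02 in control line 60, 1.01 in overexpressor line 55 and 1.19 in overexpressor line 51. For the 832 genes down in line 56 these medians were -1.05, -0.71 and -0.94. For the 1683 genes up in line 60 the medians in lines 56, 55 and 51 were 0.55, 0.47 and 0.87, and for the 3137 genes down they were -0.31, -0.27 and -0.73. Under the normexp setting the last 3 medians were positive, at 0.06, 0.68 and 0.91. There the genes were chosen anew, and a few spots distorted the fit of the 0 h array of line 60 used to choose them. Line 51 shares slide 2 with line 60, and line 55 shares slide 1 with line 56. Carry-over between lines of the same slide can hold slide differences, so the medians do not rank the lines by response.

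The effect of overexpression before nitrate was asked by comparing the genotypes at 0 h. No gene passed by limma, with 460 at an unadjusted p under 0.05, fewer than the 1134 expected by chance. The model without a block leaves the slide difference in the spread. With the slide as a block 971 were under 0.05, and 0 passed. Named as not passing were MybSt1-like Os05g0442400 (at least 4.08-fold higher, adjusted p = 0.712), the DREB1E-like Os02g0676800 (at least 3.31-fold lower), a cytochrome P450 (Os01g0627900, log2 difference 1.51 ± 0.29, SE, n = 2 lines), a carotenoid oxygenase (Os02g0704000, 1.36), a pyruvate or phosphoenolpyruvate kinase domain protein (Os12g0189300, 1.21), a lipid transfer protein (Os10g0554800, -1.90), a zinc finger protein (Os03g0421000, -3.07) and NIGT1. Light-harvesting and photosystem proteins had a median of 0.15 with 28 of 41 genes above 0 and 0 passing alone or when adjusted over the list alone (adjusted p = 0.00507, and adjusted p = 0.606 with an estimated correlation). The median was 0.46 on slide 1 and -0.05 on slide 2, and without control line 56 it was -0.02 (adjusted p = 0.708). Without overexpressor line 55 it was 0.08 (adjusted p = 0.352). Leaving out control line 56 called 1 gene.

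After 2 h of nitrate the genotypes were compared in the same way. No gene passed by limma, with 741 at an unadjusted p under 0.05 and 1134 expected by chance. With the slide as a block 1381 were under 0.05, above that number, and 0 passed. Named as not passing were the eIF-6-like Os01g0280500 (at least 24.0-fold higher, adjusted p = 0.519), an Exo70 exocyst subunit (Os08g0232700, lower and then not well above background), ubiquitin (Os09g0483400, log2 difference 2.42 ± 0.33, SE, n = 2 lines), the DREB1E-like Os02g0676800 (at least 4.79-fold higher), a protein kinase (Os02g0615500, 2.08), a zinc finger protein (Os02g0681200, -1.97), a protein phosphatase 2C (Os02g0599200, -1.67) and a low molecular weight heat shock protein (Os02g0758000, -2.79). Genes of cytokinin response and metabolism had a median of 0.60 with 10 of 12 above 0 (adjusted p = 0.00211, and adjusted p = 0.559 with an estimated correlation), 0.60 on slide 1 and 0.69 on slide 2. The type-A response regulators Os11g0143300 and Os12g0139400, which are induced by cytokinin, had differences of 1.46 and 1.42 that did not pass. Core histones had a median of 0.25 with 27 of 32 above 0 (adjusted p = 0.000756, and adjusted p = 0.559 with an estimated correlation), 0.28 on slide 1 and 0.15 on slide 2. In both lists 0 genes passed alone and 0 when adjusted over the list alone. Without control line 56 the adjusted p was 0.0920 for cytokinin genes and 0.0714 for histones, with medians of 0.51 and 0.17, and without overexpressor line 55 it was 0.0557 and 0.0707, with medians of 1.06 and 0.22. The histone call was also lost with normexp (0.27, adjusted p = 0.463). Without overexpressor line 51, 20 genes were called, all lower, and without control line 60, 1 gene.

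Whether the nitrate response differed between the genotypes was tested as an interaction. No gene passed by limma, with 321 at an unadjusted p under 0.05 against 1134 expected by chance, and 13 were called without overexpressor line 51 at 2 h, 1 higher and 12 lower. With the slide as a block 685 were under 0.05 unadjusted, and 938 with the line as a replicate block, with 0 passing in either. The smallest adjusted p without a block, 0.137, was that of the DREB1E-like Os02g0676800. Its 2 dimmer groups were not well above background, and the difference was at least 4.16 on slide 1 and 3.81 on slide 2. Also not passing were an ERF4-like factor (Os02g0764700, difference 4.34 ± 0.75, SE, n = 2 lines), the lipid transfer protein Os10g0554800 (3.47), the protein phosphatase 2C Os02g0599200 (-1.36), a heat stress factor similar to Spl7 (Os04g0568700, -1.95) and a caleosin (Os06g0254600, -1.98). The eIF-6-like and Exo70 genes were likewise among those of smallest unadjusted p, but 3 and 2 of their groups were not well above background. Light-harvesting and photosystem proteins had a median of -0.27 with 8 of 41 genes above 0 (adjusted p = 0.000115, and adjusted p = 0.559 with an estimated correlation), -0.48 on slide 1 and -0.16 on slide 2. Chlorophyll synthesis had a median of -0.25 with 1 of 11 above 0 (adjusted p = 0.0312, and adjusted p = 0.559 with an estimated correlation), -0.54 on slide 1 and -0.03 on slide 2. Cytokinin genes had a median of 0.55 with 11 of 12 above 0 (adjusted p = 0.0264, and adjusted p = 0.559 with an estimated correlation), 0.46 on slide 1 and 0.89 on slide 2. In each of these lists 0 genes passed alone and 0 when adjusted over the list alone.

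Each of these list calls was lost when certain single arrays were left out. The light-harvesting call was lost without control line 56 at 0 h (-0.06, adjusted p = 0.719) or overexpressor line 51 at 2 h (-0.09, adjusted p = 0.112). The cytokinin call was lost without control line 60 at 0 h (0.18), control line 56 at 2 h (0.25), overexpressor line 55 at 0 h (0.41) or 2 h (0.86), or overexpressor line 51 at 2 h (0.28), so its median grew in 1 of these cases. It was also lost with normexp, where the median was 2.09 (adjusted p = 0.303), with no filter on dim probes (0.48, adjusted p = 0.0672) and without both 0 h arrays of slide 2 (0.25, adjusted p = 0.225). The chlorophyll synthesis call was lost without control line 56 at 0 h (-0.33), control line 60 at 2 h (-0.29), overexpressor line 55 at 0 h (-0.17) or 2 h (-0.33), or overexpressor line 51 at 2 h (-0.31), where the median was larger in size in 4 of the 5 cases. It was also lost with quantile normalization (-0.23, adjusted p = 0.137), no filter on dim probes (-0.23, adjusted p = 0.0867) and the mean over all probes (-0.22, adjusted p = 0.128).

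Without a block the other tested lists did not pass in any of the 5 comparisons. Their smallest adjusted p came with a median of 0.31 for ammonium assimilation and asparagine synthesis in the controls (0.0864), 0.30 for ammonium transport at 2 h (0.210), 0.11 for organic acid supply at 2 h (0.357) and 0.14 for GARP and related factors in the overexpressors (0.0703). It came with -0.33 for phosphate starvation in the overexpressors (0.335), 0.24 for clock genes in the controls (0.191), -0.03 for heat shock proteins at 2 h (0.108) and 0.25 for pathogenesis-related proteins in the interaction (0.0942). It came with 0.16 for sulfate uptake and assimilation at 0 h (0.154), -0.30 for starch and trehalose metabolism in the overexpressors (0.201), and 0.30 for early auxin response (0.0707) and 0.40 for seed storage proteins (0.0878) in the interaction. Reference genes had -0.11 at 0 h (0.129). Root markers, with 3 loci kept as an alternative chosen after seeing the data, had adjusted p between 0.268 and 0.987. With the line as a replicate block some of these passed: pathogenesis-related proteins in the interaction (adjusted p = 0.00617) and the overexpressors (0.0404), early auxin response in the interaction (0.0269), ammonium assimilation in the controls (0.0339) and GARP factors in the overexpressors (0.0404). In the overexpressors cytokinin genes (median 0.65) and chlorophyll synthesis (median -0.35) also passed with that block (0.0269 each) but not without it (0.0707 each). With the slide as a block, pathogenesis-related proteins (0.0247) and early auxin response (0.0360) passed in the interaction, and cytokinin genes in the overexpressors (0.0350). None of these passed with an estimated correlation, where adjusted p = 0.636 for early auxin response, 0.604 for pathogenesis-related proteins in the overexpressors and 0.559 for the others. The pathogenesis-related list was matched by description text and is mixed. Beside chitinases and thaumatins it holds loci described as pathogenesis-related transcriptional factors with an ERF domain, such as Os05g0572000 and Os08g0408500. When adjusted over the list alone, NIGT1 was lower in the overexpressors among the 7 GARP factors at both times.

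Across genes, which are not independent replicates, the overexpressor minus control differences at 0 h and at 2 h had a Pearson correlation of 0.35 and a Spearman correlation of 0.28. Splitting the same 4 lines by slide gave 0.57 and 0.50, and the remaining split gave 0.42 and 0.34, so splits that ignore genotype gave higher correlations. Within slides the Pearson correlation was 0.28 on slide 1 and 0.43 on slide 2.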

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

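The tests of the dim array, scaling and background correction for Os02g0676800, of the transgene and array brightness for NIGT1, both tests of the slide 2 counts and the normexp setting without spots darker than their background were chosen after the result was seen.

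The fitted nitrate response of the DREB1E-like gene Os02g0676800 differed between the genotypes by 4.05 on the log2 scale, lower after nitrate in both control lines and higher in both overexpressor lines, but the interaction did not pass (adjusted p = 0.137). The gene was not well above background on 4 of 8 arrays, the controls at 2 h and the overexpressors at 0 h, so 4.05 is a fitted value, and bounds are given below. The gene was flagged because both lines of each genotype moved at least 2-fold, in opposite ways between the genotypes. Slide 1, which lacks the dim 0 h array of control line 60, gave at least 4.16. A difference there was part of the selection, so it cannot decide on that array. Scaling is argued against by quantile and median settings, which gave at least 3.58 on each slide. Background correction cannot be told apart: under the normexp settings, whose offset compresses dim signals, the bound was as low as 1.14, and without spots darker than their background overexpressor line 51 had a response bound of -0.033. The dim array and differences between single lines stay open, as does overexpression, which the interaction tested.

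The NIGT1 probes gave less signal in the arrays labelled overexpressor than in the controls. Taking the labels as given, a probe that measures the transgene would be higher there, while the difference at 0 h was at most -2.80 on either slide and at most -0.67 under the normexp settings. Dimmer overexpressor arrays are argued against by the unscaled 75th percentile at 0 h, which differed by -0.23 on slide 1 and 1.14 on slide 2 on the log2 scale. Exchanged genotype labels were not tested and stay open, as does a transgene that lacks the probe's sequence. No biological explanation was tested.

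More genes changed at least 2-fold after nitrate on slide 2 than on slide 1: 4820 in control line 60 and 1685 in line 56, a ratio of 2.86. Arrays of the 2 control lines correlated with r = 0.952 at 0 h and 0.977 at 2 h, and those of the overexpressor lines with 0.944 and 0.948, so the overexpressor lines differed at both times. The dim control array cannot be told apart from the line or slide, since line 51, with no dim array, had 1.67 times as many such genes as line 55, above 1 but below the ratio in the controls. RNA from roots cannot be told apart either. The median of 3 marker loci was at least 0.18 higher at 0 h on slide 2, but they include Os02g0662100, whose description names another protein. In the controls and overexpressors Os02g0662100 differed by 2.81 and 2.61, Os02g0745100 by 1.64 and 0.18, and Os03g0667500 by -1.28 and -2.42. RCc3, an abundant root transcript, Os03g0107300 and the RCc2-like Os10g0349300 were not well above background on any array. The RCc2 locus Os10g0551800 was well above background on the 0 h array of control line 56 and the 2 h array of overexpressor line 51. It was not on either 0 h array of slide 2. The seed storage list had higher medians at 0 h on slide 2 than on slide 1. They were 0.97 and -0.18 in the controls, and -0.09 and -0.89 in the overexpressors. This list was matched by description text, and 21 of its 58 loci were tested. It also holds Os07g0290200, described by a domain named for lipid transfer, seed storage and trypsin-alpha amylase inhibitor proteins. The medians are therefore not a clear marker of seed tissue, and line, slide and tissue stay open.

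The difference in nitrate response between the genotypes passed for 3 lists, with medians of -0.27 for light-harvesting and photosystem proteins, -0.25 for chlorophyll synthesis and 0.55 for cytokinin response and metabolism. None of the 3 passed with an estimated correlation (adjusted p = 0.559 each) or with fry (adjusted p = 0.712, 0.545 and 0.571), and each call was lost without certain single arrays.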

How the results depend on the processing

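Leaving out both 0 h arrays of slide 2, normexp without spots darker than their background, and the slide block for lists were chosen after the result was seen. The control and overexpressor nitrate counts were 25 and 49, and became 0 and 0 with normexp, 8 and 20 with no filter on dim probes, 8 and 7 with the line as a replicate block, 5 and 0 with only the arrays compared, and 0 and 0 without both 0 h arrays of slide 2. The control count was 14 with the filter on all arrays, and the overexpressor count 100 with the slide as a block. At least 2-fold on both slides, without a test, were 863 and 972 genes, and 254, 334 and 488 for the genotype at 0 h, at 2 h and the interaction. Leaving out single arrays gave counts of 0 to 4 in the controls, 5 to 32 in the overexpressors, 0 to 1 and 0 to 20 for the genotype at 0 h and 2 h, 0 to 13 for the interaction and 12 to 26 list calls, with 1 group then held by 1 array and the spread taken from the others. The NIGT1 differences then ranged from 4.12 to 4.32 in the controls, 4.81 to 6.60 in the overexpressors, -4.51 to -4.45 and -3.89 to -2.10 for the genotype, and 0.59 to 2.38 for the interaction; those that use the overexpressors at 0 h rest on signals not well above background and show no stability. The NIGT1 call in the overexpressors was lost with normexp (2.37), no filter (5.70), the mean over probes (4.48), normexp without dark spots (1.74), the line block (5.70), without both arrays (5.71), with only the arrays compared (5.70), and without overexpressor line 55 at 0 h (5.69, adjusted p = 0.142) or line 51 at 0 h (5.71, adjusted p = 0.171). List calls numbered 14, and 44 with normexp, 29 with normexp without dark spots, 0 with an estimated correlation, 5 with fry (nitrate reduction and reductant supply in both genotypes and nitrate transport in the overexpressors) and 17 with the slide as a block, which kept all 14. With the line as a replicate block 5, 8 and 5 lists passed in the controls, the overexpressors and the interaction, against 4, 4 and 3 without it.

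Normexp as planned gave a median over all genes of -0.62 in the controls and 0.85 in the interaction, against -0.030 and 0.032 with the processed signal. A few spots darker than their background raised the fitted noise on several arrays. It was 951 for control line 60 at 0 h, against 0.96 without them. It was 288 against 1.11 for overexpressor line 51 at 2 h, and 81.0 against 2.73 for line 55 at 2 h. Without such spots the medians were -0.17 and 0.12. Under normexp as planned many list medians changed sign. Nitrate transport in the controls, a called list, had -0.69 and no longer passed (adjusted p = 0.181). The list test turned direction and passed for light-harvesting (median 0.16) and chlorophyll synthesis (0.16) in the controls, ribosomal proteins (0.15) and reference genes (0.044) at 0 h, ribosomal proteins at 2 h (0.028, a median that kept its sign), and organic acid supply (-0.0054), ribosomal proteins (-0.14) and reference genes (-0.048) in the interaction. Leaving out single arrays, ribosomal proteins ranged from -0.32 to 0.17 at 0 h and from -0.093 to 0.37 in the interaction, turning without overexpressor line 51 at 0 h. Light-harvesting at 0 h ranged from -0.019 to 0.34, turning without control line 56. The carry-over under normexp for genes up in line 56 was 0.20, 1.17 and 1.42 in lines 60, 55 and 51, for genes down -0.48 and -0.71 in lines 55 and 51, for genes up in line 60 0.22, 0.032 and 0.20, and for genes down 0.057, 0.68 and 0.91. Genes were chosen anew under each setting, as they were for quantile normalization, which gave 1.33 in line 60 for genes up in line 56. The 4-fold selection gave 1.99, 1.91 and 2.14, then -1.62, -1.30 and -1.48, and 1.05, 0.88 and 1.28 for genes up in line 60. These medians come from arrays not used to choose the genes, so a stricter cut does not raise them by construction. Lines on the same slide can still share slide differences. The correlation of the genotype differences was -0.74 under normexp. Other causes were not tested. With the line as a random block (correlation 0.48) limma called 0 genes between the genotypes, with 350 at 0 h and 743 at 2 h at an unadjusted p under 0.05 and 1134 expected by chance. The slide as a block gave 971 and 1381 such genes, also with 0 called. Of the single genes and lists, 9860 values stayed on their side of the threshold (values that passed in neither setting could change sign), 283 fell short of it, 120 newly passed it and 11 turned. Signal over background limits what dim genes can show.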

Other observations

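Among the genes called by limma after nitrate in the overexpressors were Os02g0630300, similar to gibberellin 2-oxidase 3, which rose by log2 4.61 ± 0.37 (SE, adjusted p = 0.0225), and Os01g0757200, similar to GA 2-oxidase 4, which rose by 3.96 ± 0.35 (adjusted p = 0.0241), each in 2 of 2 lines. In the controls their differences were 2.71 (adjusted p = 0.109) and 1.86 (adjusted p = 0.209), and the difference in response did not pass for either. They were chosen after their values were seen and belong to no list fixed beforehand, and gibberellin genes were not tested as a group. Other loci with such descriptions did not pass in the overexpressors, with differences of -0.012 for Os05g0158700, -1.50 for Os05g0514600 and -1.43 for Os05g0560900.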
